A study of Danio rerio with 9 samples.

How the data were processed

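Gene expression was measured by strand-specific sequencing of polyadenylated RNA from zebrafish of the AB strain at 96 h after fertilization. Per the labels, the 9 samples fell into 3 groups of 3: a solvent control with 0.01% DMSO, 16 µM perfluorobutane sulfonate (PFBS) and 32 µM PFBS. Each sample pooled 15 embryos, and 3 separate experiments each gave 1 sample per group, but the labels do not say which sample came from which experiment. The labels give a growth temperature of 37 °C, which is unusually warm for zebrafish, and whether it is an entry error is not known. Group membership was taken from the exposure label of each sample.

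The authors deposited 3 tables, 1 for each pair of groups. Per the file headers, the authors gave each group's expression as the log2 of its FPKM (fragments scaled to transcript length and to the mapped total), 1 value per group, together with a log2 ratio of the groups, a q-value and a yes or no call. The deposited log2 ratio is the second group minus the first to within 0.011, which was checked on every row, so a positive value means a higher level with PFBS or with the higher dose. A value of -10 on the log2 scale stands for an FPKM of 0. The authors' deposited calls are the rows with a q-value under 0.05, also checked on every row. Per the submitters' processing notes the tool was Cufflinks and the genome build danRer7. The aligner, the version of each tool, the gene annotation and the statistical test behind the q-values are not given in the sources used here. Row identifiers differed between the tables, so each table was read as a separate transcript assembly, and loci are given as the tables give them.

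The tables hold no value per sample, no read count, no standard error and no test statistic. The depth of each sample is therefore unknown, no spread between replicates could be computed, and the q-values rest on the authors' test of 3 samples against 3. Because the design had planned a signed statistic for the gene list tests, which the tables lack, the log2 ratio was used in its place. Comparisons were read within a table, and values set side by side from different tables are ratios formed within each table.

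Unadjusted p-values were recovered from the deposited q-values by undoing the Benjamini-Hochberg adjustment (q times rank divided by the number of rows, with tied q-values at their largest rank); they are upper bounds where q-values are tied. The smallest recovered p-value was 5e-05 in each table, shared by most of the called rows, so that called genes could seldom be ranked by p. Rows that name 1 gene were used for gene names and lists; unnamed rows and rows pooling several names were counted but not named. Of the gene names, 10601 of 11968, 10369 of 11685 and 10588 of 11946 in the tables for 16 µM, 32 µM and 32 against 16 µM were current symbols of the RefSeq annotation of GRCz12tu, and 1246, 1202 and 1238 others matched 1 current symbol as a synonym; that annotation served for names alone.

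A total of 28 gene lists for organs, metabolic pathways and stress responses were fixed before the data were examined, as were the thresholds and the rule for named genes. The rule took, per comparison, the 10 called genes with the largest increase and the 10 with the largest decrease that reached 1 FPKM in the higher group, the 5 called genes with the highest level, up to 4 called members of each list by smallest p, up to 2 members not called of the pancreas and lipid lists, and up to 10 genes called at both doses. The values of 1 gene that this rule selects are not reported here. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the log2 ratios, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 27 lists tested in each comparison; the list of vitellogenins and oestrogen targets had at most 1 measured member and was not tested. A correlation between genes could not be estimated without values per sample, so a preset correlation of 0.05 served as the stricter alternative. These tests set the genes of a list against other genes, so their p-values measure no spread between samples. The background was the single-gene rows, 1 row per name with the highest mean level. Each list's median was also placed among 10000 random lists matched on expression in 20 bins. Called lists are given with their percentile where it lay within the central 95% of the random lists. A further 6 lists were put together after the data were seen and appear in the closing section alone.

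The 2 doses were compared on 11206 rows joined by gene name, or by identical locus for unnamed rows. Because both doses were set against the same control, 1000 simulations of unchanged groups gave the overlap and correlation that a shared control produces with no effect. Each group's error was taken from the ratios of 32 to 16 µM in 20 expression bins, so the control was assumed to vary as the PFBS groups do. The rows with the largest ratios relative to that error were counted as called, in the numbers observed. Spread particular to a gene and the authors' own test were not modelled. With 3 control samples and no value per sample, the controls could not be split. On simulated data in which genes varied independently, lists shifted by 0.2 on the log2 scale were called in 100% of 40 cases in each comparison. Lists shifted by 0.1 were called in 52.5% at 16 µM, 47.5% at 32 µM and 67.5% for 32 against 16 µM. Unshifted lists were called in 0.943%, 0.254% and 0.504% of cases. These rates do not cover lists whose genes vary together, for which errors may be more frequent. The alternatives were other q-value thresholds, expression minimums of 1 and 5 FPKM, minimum changes, log2 values with a pseudocount of 1 FPKM, centred ratios, other preset correlations, ranks, control values from the other table and, added after the data were seen, leaving out rows that share an identical locus or genes that stand in several lists. Other computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.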

Results

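Zebrafish embryos were exposed to PFBS, a perfluorinated sulfonate with a chain of 4 carbons, and whole animals were collected at 96 h after fertilization. The groups compared were the solvent control, 16 µM and 32 µM PFBS, each with 3 samples of 15 pooled embryos from separate experiments. Expression is given as group FPKM from the authors' deposited tables, which hold 1 value per group, so no level or fold change below has a standard error and the depth per sample is unknown. Whether a difference exceeds the spread between replicates therefore rests on the authors' q-values. The camera p-values of gene lists compare genes with other genes and do not show that a list differs beyond the spread between samples. Fold changes are log2 ratios, and a gene is said to have risen or fallen where its q-value in the authors' deposited table was under 0.05.

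The first comparison asked which genes differed between 16 µM PFBS and the control. In the authors' deposited table, cyp1a, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 1.49 (chromosome 18, 4974675 to 4985563, danRer7; 6.73 to 18.9 FPKM, q = 0.0219), and cyp1b1, another target of that receptor, rose by 0.58. The core clock gene nr1d1, which encodes the transcriptional repressor Rev-erb alpha, fell by 1.34 in the authors' deposited table (chromosome 3, 23779861 to 23787461; 8.11 to 3.23 FPKM, q = 0.0219). Pancreatic amylase amy2a rose by 0.40 in the authors' deposited table (chromosome 2, 15433345 to 15447553; 20.4 to 27.1 FPKM, q = 0.0219), and the blue cone opsin opn1sw2 rose by 0.32. In all, 76 of 29280 rows of the authors' deposited table were called, 33 higher and 43 lower, of which 45 named a single gene (19 higher and 26 lower), 27 had no name and 4 pooled several names.

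Among the 16 measured genes of xenobiotic metabolism, 3 rose at 16 µM in the authors' deposited table, cyp1a, cyp1b1 and the pregnane X receptor target cyp3a65 (0.36), and the other 13 did not pass the test. The count was 4 higher when adjusted over the list alone. As a whole the list was higher than other genes (median 0.08, camera adjusted p = 2.76e-09). Of 32 circadian clock genes, 7 fell and none rose in the authors' deposited table. These included nr1d1, dbpb (-0.80), per1b (-0.64) and nr1d2a (-0.46), which encode clock repressors or clock-controlled transcription factors. Clock genes lower adjusted over the list alone numbered 9, and the list median was -0.07 (camera adjusted p = 6.28e-05). On ranks the adjusted p was 0.127, within a range of 2.17e-06 to 0.127 over the alternatives. Of 29 photoreceptor genes, the cone and rod transducin subunits gngt2a (0.36) and gngt1 (0.36) and opn1sw2 rose in the authors' deposited table. For photoreceptors 5 genes were higher and 1 lower adjusted over the list alone, with a list median of 0.10 (camera adjusted p = 0.02). With a preset correlation of 0.05 the adjusted p was 0.183, within a range of 0.000257 to 0.183.

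The digestive organs stood out as lists more than as single genes at 16 µM. All 11 measured exocrine pancreas genes had a positive log2 ratio in the authors' deposited table, but amy2a alone passed the test. Trypsin (try) had 0.17 and carboxypeptidase cpb1 0.16, both with q = 0.998. The exocrine pancreas list had a median of 0.14 (camera adjusted p = 0.00484), and 1 member was higher adjusted over the list alone. The intestine list, with 17 measured genes of which none was called, had a median of 0.12 (camera adjusted p = 0.00484), and 2 members were higher adjusted over the list alone; 4 of its genes also stand in other lists. None of the 19 endocrine pancreas genes was called. In the authors' deposited table insulin (ins) had 0.12 and ghrelin (ghrl) 0.96, without passing the test. No gene of fatty acid oxidation, fatty acid and triglyceride synthesis, lipid transport or cholesterol synthesis passed the test at 16 µM, while 1 synthesis gene and 2 transport genes were higher adjusted over the list alone. Lipid transport had a median of -0.02 and a mean of -0.01 although its camera test pointed upwards (adjusted p = 0.863). Members of the lipid lists were named by smallest p, with ties going to the larger change. Ratios in the authors' deposited table were 0.32 for fads2 (q = 0.301), 0.31 for fabp6 (q = 0.202) and 0.23 for fabp2 (q = 0.276). They were 0.22 for hmgcra (q = 0.627) and 0.21 for msmo1 (q = 0.811). The ratios of acsl1b (0.50) and elovl2 (0.28) both had q = 0.998. Among the many genes tied at that q these were selected by size of change.

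Other genes with large changes at 16 µM included the immune gene irg1l (-0.83), the relaxin receptor gene rxfp2b (-0.68), the annexin gene anxa6 (-0.55), the mitochondrial uncoupling protein gene ucp3 (-0.49) and ankrd9 (-0.46) among those that fell in the authors' deposited table. Those that rose in the authors' deposited table included zgc:153968 (0.53), plekhf1 (0.47), zgc:193593 (0.42) and the sulfotransferase gene sult6b1 (0.39). The called genes with the highest levels in the authors' deposited table were gngt2b (0.34), LOC795545 (0.34), opn1sw2, LOC100537295 (0.36) and the transcription factor gene cebpd, which fell (-0.38). The liver carboxylesterase gene ces3 fell by 0.32 in the authors' deposited table, the only one of 28 liver genes to pass the test; adjusted over the list alone 2 were lower. Rows named for microRNA loci were among those with the largest ratios in the authors' deposited table: mir190b at 2.44, mir214a at 1.86 and mir133c at -1.40; the mir214a row shares its locus with another row. A row named mpx, the gene of neutrophil myeloperoxidase, rose by 1.60 in the authors' deposited table, but its locus is exactly that of cyp1a, and the pair of rows named mpx on chromosome 10 had ratios of 0.07 and -0.17, both with q = 0.998.

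Of the 76 rows called at 16 µM, 67 had the smallest q of the table, 0.0219, so none passed a q-value under 0.01. The median size of change of the called rows was 0.45 on the log2 scale, and 14 changed at least 2-fold. Across all expressed rows the median log2 ratio was 0. The 22 lists not called at 16 µM had camera adjusted p-values between 0.0813 and 0.977. The glucocorticoid, oxidative stress, cholesterol synthesis and skeletal muscle lists were called at 16 µM under some alternatives.

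The second comparison set 32 µM PFBS against the same control. Pancreatic digestive enzyme genes rose together: in the authors' deposited table the elastase gene ela3l rose by 0.62 (chromosome 5, 27756147 to 27763331; 71.5 to 109.1 FPKM, q = 0.00521), amy2a by 0.58, the elastase gene ela2 by 0.35 and the carboxypeptidase gene cpa4 by 0.29. Genes of cholesterol synthesis also rose, among them squalene epoxidase sqlea (0.41), HMG-CoA reductase hmgcra (0.35), cyp51 (0.34) and sc5d (0.33) in the authors' deposited table. Genes expressed mainly in the liver fell, with ces3 at -0.57, a2ml at -0.32, agt at -0.23 and ambp at -0.23 in the authors' deposited table. The clock genes nr1d1 (-1.51), dbpb (-0.95), per1b (-0.80) and tefa (-0.66) fell in the authors' deposited table, and the matrix metalloproteinase gene mmp9 rose by 1.17 (chromosome 8, 25134467 to 25148890; 4.32 to 9.71 FPKM). In all, 492 of 26901 rows of the authors' deposited table were called, 258 higher and 234 lower, of which 276 named a single gene (120 higher and 156 lower), 197 had no name and 19 pooled several names. All 26901 rows reached 1 FPKM in at least 1 group, against 27572 of 29280 rows at 16 µM. The row totals of the 2 doses therefore cover unlike sets. Among the 373 called rows at 5 FPKM or more, 169 were higher, so that higher rows were no longer the majority.

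Of 11 exocrine pancreas genes, 9 rose at 32 µM in the authors' deposited table and none fell. The members not called were the zymogen granule gene sycn.2 (0.27, q = 0.512) and the transcription factor gene ptf1a (0.10, q = 0.899). That count was also 9 adjusted over the list alone, and the list median was 0.28 (camera adjusted p = 4.02e-10). A further 4 rows pooled a member of this list with other names, and 3 of them were called higher. Pooled rows of other lists called at 32 µM were 2 of 10 higher for xenobiotic metabolism and, all lower, 2 of 2 for the liver, 1 of 2 for lipid transport, 1 of 2 for the intestine and 1 of 1 for heat shock. None of 18 endocrine pancreas genes passed the test (camera adjusted p = 0.420). The smallest p-values belonged to pcsk2 (0.18) and isl1 (-0.15) in the authors' deposited table. In the endocrine list 1 gene was higher and 1 lower adjusted over the list alone. In the intestine list 3 of 16 genes rose in the authors' deposited table, the amino acid transporter gene slc6a19b (0.35), the fatty acid binding protein gene fabp2 (0.23) and the brush border gene vil1 (0.20). Intestine genes higher adjusted over the list alone numbered 7, and the list median was 0.19 (camera adjusted p = 0.000304).

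Of 28 liver genes, 12 fell and none rose at 32 µM in the authors' deposited table, and 5 of the list's genes also stand in other lists. The liver counts were 16 lower and 1 higher adjusted over the list alone, with a list median of -0.18 (camera adjusted p = 0.00245). With a preset correlation of 0.05 the adjusted p was 0.0569, within a range of 9.78e-05 to 0.0569. The vitamin D binding protein gene gc has 2 rows with the same ratio of -0.30 in the authors' deposited table, only 1 of them called (q = 0.0125 and 0.141), and the list counts the row that was not called.

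Lipid genes moved in both directions at 32 µM. In cholesterol synthesis 6 of 23 genes rose and none fell in the authors' deposited table, while mvk (-0.37, q = 0.181) and fdps (0.15, q = 0.228) did not pass the test. Cholesterol genes adjusted over the list alone were 8 higher and 1 lower, and the list median was 0.14 (camera adjusted p = 0.000201). In fatty acid and triglyceride synthesis the desaturase gene fads2 (0.54) and the elongase gene elovl2 (0.47), which make long-chain polyunsaturated fatty acids, rose in the authors' deposited table. Not called there were lpin1 and dgat1a, each at 0.15. Of these 17 genes 3 were higher adjusted over the list alone (median 0.03, camera adjusted p = 0.0186). The adjusted p of this list was 0.0969 with a preset correlation of 0.05, within a range of 0.00473 to 0.0969. Its median lay at percentile 96.1 of the matched random lists. In fatty acid oxidation 2 of 33 genes rose in the authors' deposited table, among them hadhab (0.35), with acsl1b (0.63) and acads (-0.15) not called. Oxidation genes higher adjusted over the list alone numbered 3, and the list was not called (median -0.01, mean 0.03, camera direction upwards, adjusted p = 0.283). In lipid transport 3 of 25 genes rose and 4 fell in the authors' deposited table, with the low-density lipoprotein receptor gene ldlra (0.31) and fabp2 higher and the apolipoprotein genes apoa1a (-0.27) and apom (-0.27) lower. The members of lipid transport closest to the threshold were fabp6 (0.24, q = 0.0810) and apobb.1 (-0.19, q = 0.111) in the authors' deposited table. The transport list had 4 genes higher and 5 lower adjusted over the list alone and was not called (camera adjusted p = 0.522).

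Of the 16 genes of xenobiotic metabolism, cyp2k18 (0.85), cyp1a (0.82) and cyp3a65 (0.54) rose at 32 µM in the authors' deposited table. Of these genes 6 were higher adjusted over the list alone, and the list median was 0.17 (camera adjusted p = 1.67e-08). Of 26 oxidative stress genes, abcc2 (0.33) and nfe2l2a (0.23), which encodes Nrf2, rose in the authors' deposited table. That list had 3 genes higher adjusted over the list alone and was not called (camera adjusted p = 0.283). Among glucocorticoid targets fkbp5 (0.42) and pck1 (0.19) rose and tat (-0.50) fell in the authors' deposited table, and adjusted over the list alone 4 genes were higher and 1 lower. The glucocorticoid list was not called, with a median of -0.03, a mean of 0.01 and an upward camera test (adjusted p = 0.664).

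Of 32 clock genes, 4 rose and 9 fell at 32 µM in the authors' deposited table, and adjusted over the list alone 8 were higher and 11 lower. The camera test placed the list lower than other genes (adjusted p = 0.00245). Its mean was -0.12 and its median 0.00, so the median does not share the sign of the test. Among the matched random lists that median lay at percentile 77.9, on the higher side. With a preset correlation of 0.05 the adjusted p was 0.0569, and on ranks 0.849, the top of a range from 0.000316. The innate immunity list was called higher (adjusted p = 0.0186, median 0.01), with mmp9 and the row named mpx at the cyp1a locus (0.89) higher and the complement genes cfd (-0.32), c3a.1 (-0.24) and 1 other lower in the authors' deposited table. Adjusted over the list alone the counts were 3 higher and 5 lower. The adjusted p of that list was 0.0969 with a preset correlation of 0.05, 0.239 without rows that share a locus and 0.849 on ranks, within a range of 0.00921 to 0.849. The median of the immunity list lay at percentile 83.7 of the matched random lists. Skeletal muscle genes were lower as a list (median -0.10, camera adjusted p = 0.0460), and pvalb3 (-0.35) and acta1a (-0.23) fell in the authors' deposited table, with 3 lower adjusted over the list alone. The adjusted p of the muscle list was 0.192 with a preset correlation of 0.05 and 0.0663 without rows that share a locus, within a range of 0.00260 to 0.192. Lens crystallins were lower as a list with none of 22 genes called (median -0.09, camera adjusted p = 0.0260). For the lens list the adjusted p was 0.131 with the same preset correlation and 0.0663 without rows that share a locus, within a range of 0.0117 to 0.131.

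**Figure D1:**
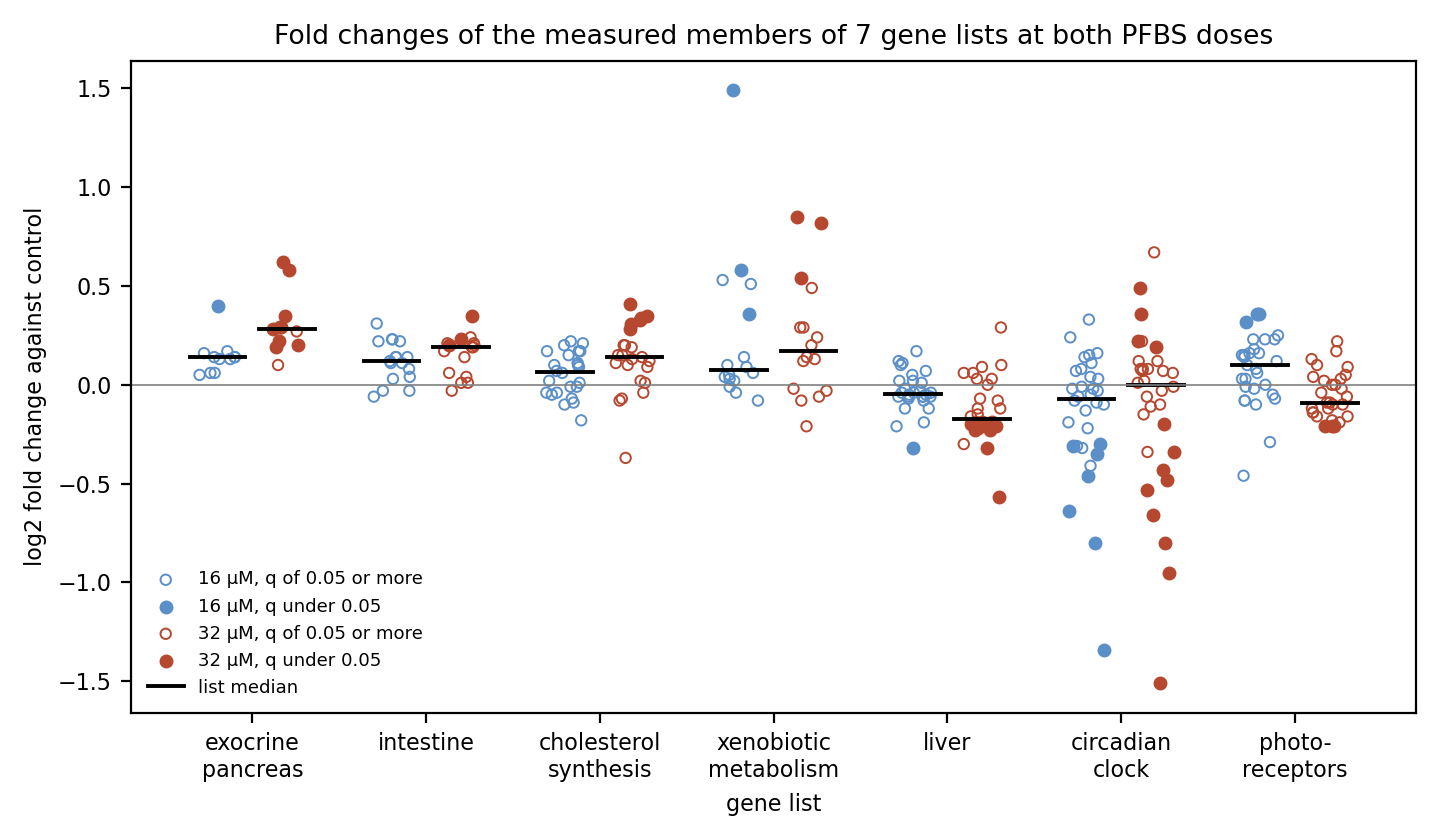
Log2 fold changes against the control (vertical axis) of the measured members of 7 gene lists (horizontal axis) at 16 µM (blue) and 32 µM PFBS (red), from the authors' deposited tables. Each point is 1 gene, filled where its q-value was under 0.05, and black bars are list medians; 9 of 11 exocrine pancreas genes were called higher and 12 of 28 liver genes lower at 32 µM.

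Lists not called at 32 µM still held single genes past the threshold. In the authors' deposited table, the photoreceptor genes arr3a, pde6c and saga fell by 0.21 each (camera adjusted p of the list 0.355). The DNA replication genes mcm4 (-0.20) and mcm6 (-0.19), the cartilage and fin matrix genes col9a1b (-0.30) and and1 (-0.20), the myosin light chain gene cmlc1 (-0.33), myoglobin mb (-0.21), the keratin gene krt8 (-0.21) and the gluconeogenic gene fbp1b (-0.27) fell in the authors' deposited table. No member of the thyroid, heat shock, neuron and glia, erythrocyte or retinoid lists was called at 32 µM on a row of its own, and the 17 lists without a call had camera adjusted p-values between 0.129 and 0.874. On ranks the cartilage, epidermis and erythrocyte lists were called at 32 µM.

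The largest increases at 32 µM outside the lists, in the authors' deposited table, were those of the mir135b row (3.56), coro7 (1.09), zgc:92590 (1.01), the elongation factor gene eef1a1l2 (0.72), pnpla7a (0.69) and the astacin protease gene c6ast4 (0.68). A second row named coro7 had 0.43 (q = 0.0955) in the authors' deposited table. The largest decreases there were those of the mir133c row (-1.45), the D-amino acid oxidase gene dao.1 (-1.12), the acid phosphatase gene acp5a (-0.95), znf395b (-0.63), the melanosome gene pmelb (-0.62) and havcr1 (-0.61). The called genes with the highest levels in the authors' deposited table were apoa2 (-0.22), apoa1a, fabp1b.1 (0.21), the methyltransferase gene bhmt (-0.21) and the actin-binding gene pfn1 (-0.18). Rows named h2afy2 lay at 2 loci of chromosome 13 and moved in opposite directions in the authors' deposited table (-0.54 and 0.25, both q = 0.00521), as did those named uqcrfs1 at 2 loci of chromosome 7 (-0.23 and 0.49). The change of either gene is therefore uncertain. The median size of change of the called rows was 0.34, 29 rows changed at least 2-fold, and the median over all expressed rows was 0.

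The third comparison set the 2 doses directly against each other. Relative to 16 µM, 32 µM PFBS gave higher mmp9 (1.1), fkbp5 (0.66), ela3l (0.49) and ela2 (0.29) and lower cyp1a (-0.67) in the authors' deposited table, each with q = 0.0194. Cone and retinal genes were lower at the higher dose: in the authors' deposited table rlbp1b had -0.54, arr3a -0.31, the retinoid isomerase gene rpe65a -0.30 and the green cone opsin opn1mw1 -0.24. In all, 96 of 29163 rows of the authors' deposited table were called, 68 higher and 28 lower at 32 µM; 52 named a single gene, 42 had no name and 2 pooled several names.

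Of 29 photoreceptor genes 3 fell from 16 to 32 µM in the authors' deposited table, 26 had a negative ratio, and 12 were lower adjusted over the list alone (median -0.14, camera adjusted p = 0.000477). Lens crystallins were also lower as a list, with none of 25 genes called (median -0.06, camera adjusted p = 0.000520). Of 11 exocrine pancreas genes 2 rose in the authors' deposited table and 4 were higher adjusted over the list alone (median 0.15, camera adjusted p = 0.0118). The members ela2l (0.22) and amy2a (0.18) did not pass the test in the authors' deposited table, and with a preset correlation of 0.05 the adjusted p was 0.0532, within a range of 0.000161 to 0.0532. The liver list was lower with none of 29 genes called and 1 lower adjusted over the list alone (median -0.10, camera adjusted p = 0.0181). With a preset correlation of 0.05 the adjusted p was 0.173, within a range of 0.00209 to 0.173. Of 13 glucocorticoid targets fkbp5 and cebpd (0.27) rose in the authors' deposited table, and 5 were higher adjusted over the list alone (median 0.07, camera adjusted p = 0.0143). On ranks the adjusted p was 0.383, with a preset correlation of 0.05 it was 0.0685 and without rows that share a locus 0.0737, within a range of 0.000383 to 0.383. The cholesterol synthesis list stayed just outside the threshold (19 of 24 genes with a positive ratio, median 0.11, camera adjusted p = 0.0519), with hmgcs1 (0.18) and cyp51 (0.17) not called in the authors' deposited table. On ranks it was called (adjusted p = 0.00420, range over the alternatives 0.00420 to 0.252). None of the genes of the endocrine pancreas, fatty acid oxidation or fatty acid synthesis lists was called. Their smallest q-values in the authors' deposited table belonged to pcsk2 (0.21, q = 0.51), hadhab (0.19, q = 0.359) and fads2 (0.23, q = 0.618). The other members named, sst2 (0.30), plin2 (0.21) and elovl2 (0.19), had q = 0.999. Among the many genes tied at that q these were selected by size of change. In lipid transport apoc1l fell (-0.26) and apoa2 (-0.19) and apom (-0.18) did not pass the test in the authors' deposited table.

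Other genes higher at 32 than at 16 µM in the authors' deposited table were eef1a1l2 (0.69), rfx3 (0.63), the cell cycle inhibitor gene cdkn1a (0.62), si:ch211-153b23.4 (0.59), the kinase gene sik1 (0.57), slc25a25a (0.51), jund (0.48), nr1d2a (0.40) and serbp1a (0.34). Others lower there were the rows mir190b (-2.36) and mir214a (-1.75), one of the rows of h2afy2 (-0.42, the other at 0.33), gstt1b (-0.37), tefa (-0.34), col9a1b (-0.32) and the keratin gene cyt1 (-0.27). The 22 lists not called had camera adjusted p-values between 0.0519 and 0.857, and 8 of the called rows changed at least 2-fold. The smallest q of that table was 0.0194, so none of its rows passed a q-value under 0.01.

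Across doses, the genes called at both with the largest mean change, leaving out names that stand on several rows of a table such as mpx, were nr1d1, the mir133c row, cyp1a, dbpb, per1b, znf395b, amy2a, tefa, zgc:153968 and cyp3a65. In the authors' deposited tables znf395b fell by 0.44 at 16 µM and 0.63 at 32 µM, tefa by 0.31 and 0.66, and zgc:153968 rose by 0.53 and 0.43. Among 11206 joined rows, 42 were called at 16 µM and 266 at 32 µM. Both doses shared 23 calls, 22 of them in the same direction (9 higher and 13 lower). The exception was sik1, at -0.38 and 0.19 in the authors' deposited tables, named here after its values were seen. Independent lists of these sizes would share 0.513 rows, and unchanged groups set against a shared control shared 9.47 on average and at most 19 in 1000 simulations. The simulations gave the control the same error as the PFBS groups. They also fixed the number of called rows at that observed and left out spread particular to a gene. The observed 22 and the simulated counts were therefore not obtained in the same way. A control with a wider spread could produce the excess in part or in whole, and the control samples could not be split. Of the 266 rows called at 32 µM, 232 had the same sign and a larger size at 32 than at 16 µM. Of the 42 called at 16 µM this held for 13. Rows selected by a call at a dose tend to have their larger size there. These counts are therefore no measure of a dose response. The same sign at both doses was seen for 37 of the 42 rows called at 16 µM (88.1%, against 96.6% in the simulations).

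Over 11189 expressed genes, which are not independent replicates, the ratios of the 2 doses had a Pearson r of 0.559 and a Spearman rho of 0.524, against a mean r of 0.50 in the simulations. Their covariance was 0.0108, against 0.00822 on average and at most 0.00885 in the simulations, a difference of 0.00256. A wider spread of the control than the simulations assumed would also raise the covariance, so the difference does not show an effect shared by the doses. When each dose took its control value from the other table r was -0.22, owing to 690 rows whose control values differed by over 0.1 between the tables. Of the 48 joined rows called between the doses, 37 were also called against the control at either dose, 12 at 16 µM and 28 at 32 µM, and 28 of the 48 had ratios of opposite sign at the 2 doses. These comparisons share samples, and no count expected without change was computed for them.

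**Figure D2:**
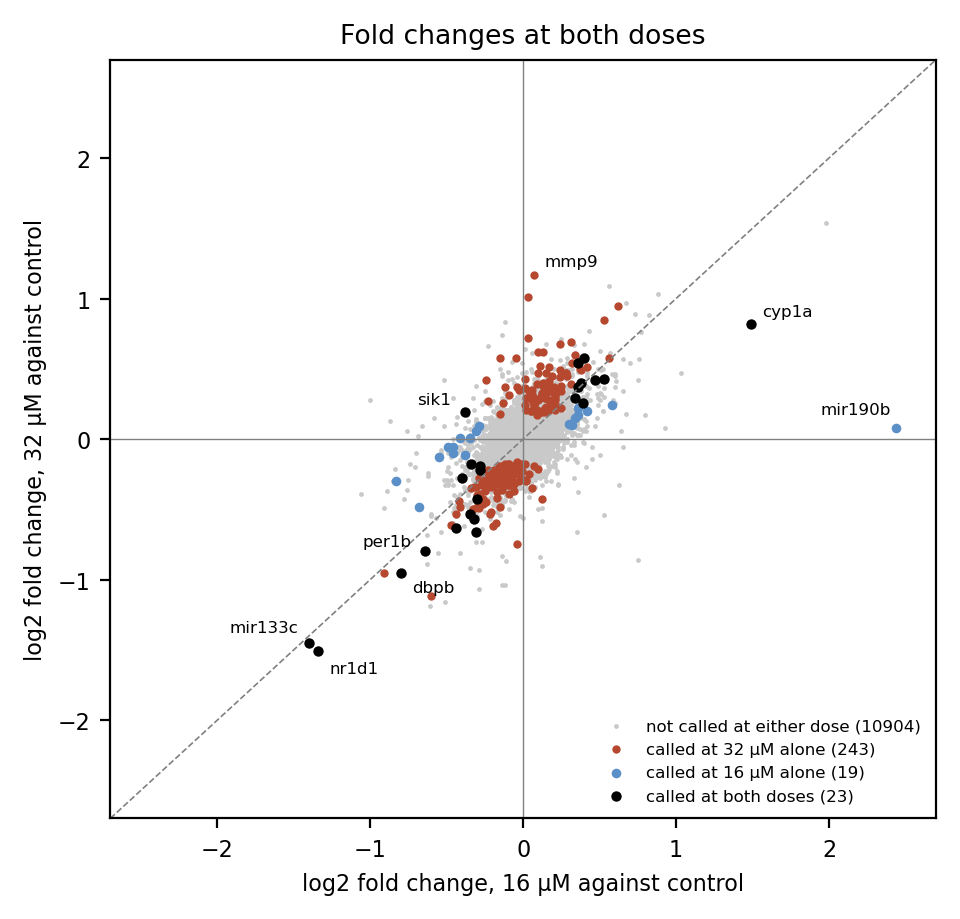
Log2 fold changes against the control of 11189 expressed genes at 16 µM (horizontal axis) and 32 µM PFBS (vertical axis), from the authors' deposited tables; the dashed line marks equal change. Points are genes not called (grey), called at 32 µM alone (red, 243), at 16 µM alone (blue, 19) or at both doses (black, 23); nr1d1, dbpb and per1b lie low on both axes, cyp1a lies below the line, and mmp9 is high at 32 µM alone.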

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

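All tests of explanations in this part were chosen after the results they bear on were seen. Only genes selected by the rule for named genes were considered here, so other genes called in both ways are not counted. Among those found in all 3 tables under a name held by 1 row in each, 22 were called both between the 2 doses and against the control at either dose. The difference between the dose groups rests on the authors' direct comparison, and the call against the control is not separate support, because the comparisons share samples and no value expected without change was computed for such double calls. For 10 of them the ratios at 16 and 32 µM had opposite signs, for 6 the same sign with a larger size at 32 µM, and for 6 the same sign with a smaller size there. In the authors' deposited table the log2 ratios of 32 over 16 µM were positive for mmp9 (1.1), eef1a1l2 (0.69), fkbp5 (0.66), rfx3 (0.63), sik1 (0.57), slc25a25a (0.51), ela3l (0.49), jund (0.48), c6ast4 (0.44), anxa6 (0.41), nr1d2a (0.40), ankrd9 (0.36), serbp1a (0.34), ela2 (0.29) and cebpd (0.27). They were negative for mir190b (-2.36), cyp1a (-0.67), rlbp1b (-0.54), tefa (-0.34), col9a1b (-0.32), arr3a (-0.31) and apoc1l (-0.26) in the authors' deposited table. The same held for 4 gene lists called between the doses and at either dose, with medians of 0.15 for the exocrine pancreas, -0.14 for photoreceptors, -0.10 for the liver and -0.06 for lens crystallins. With a preset correlation of 0.05 none of the 4 kept both calls: the exocrine pancreas and the liver lost the call between the doses (adjusted p = 0.0532 and 0.173, ranges over the alternatives 0.000161 to 0.0532 and 0.00209 to 0.173), the liver and lens crystallins that at 32 µM (0.0569 and 0.131, ranges 9.78e-05 to 0.0569 and 0.0117 to 0.131) and photoreceptors that at 16 µM (0.183, range 0.000257 to 0.183).

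Clock genes changed at both doses, and a candidate explanation is a shift of clock phase between the groups. Such a shift moves apart the genes that peak at different times. Over all 32 members of the list, the median of the arntl, clock, npas2, nfil3 and ror genes lay above that of the other clock genes. The difference was 0.27 at 16 µM and 0.27 at 32 µM (two-sided permutation tests of arm membership, p = 0.00188 and 0.00116). Both differences rest on the same control samples, so a deviation of the control alone could give both, and they are not separate support. For 32 µM set directly against 16 µM the difference was 0.08 (same permutation test, p = 0.103). The permutation also treats genes as independent and measures no spread between samples. A different hour of collection or of exposure renewal would give the same pattern of clock genes. It cannot be told apart from an effect of PFBS on the clock, since 0 samples have an hour of collection in their labels.

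Liver genes were lower while exocrine pancreas and intestine genes were higher at 32 µM. A smaller share of liver tissue alone would raise the markers of every other organ alike. The exocrine pancreas median lay 0.36 above that of 127 markers of muscle, heart, nerve, skin, blood and skeleton (0.28 against -0.08, two-sided permutation p = 2e-05, the smallest the test can give). The exocrine list was compared because it had already been called higher, so this p-value is not separate evidence. The permutation also treats genes as independent and measures no spread between samples. A shift of all ratios by the scaling stays open for the sign of each list's change. The median over all expressed rows was 0, which a scaling between groups could impose, so it cannot be told apart from a true balance. Changed numbers of cells in each organ also stay open and cannot be told apart from changed expression per cell: 0 liver genes were called higher at 32 µM, which either would allow, and no cell counts were used here. An effect of PFBS on these organs remains a hypothesis.

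The row named mpx rose with cyp1a, and signal of cyp1a at the shared locus (chromosome 18, 4974675 to 4985563) is a candidate explanation. The log2 ratios of the row and of cyp1a differed by at most 0.11 over the 3 comparisons, while the rows named mpx on chromosome 10 moved by at most 0.17. The row named mpx had the higher level, 10.5 FPKM in the control and 31.8 at 16 µM, against 6.73 and 18.9 for cyp1a. Which of the 2 rows holds the source of the signal therefore stays open. More neutrophils are argued against by the medians of -0.055 at 16 µM and -0.05 at 32 µM over 6 other neutrophil genes (lyz, ncf1, lect2l, mmp13a, coro1a and lcp1). The neutrophil granule gene mmp9 did rise at 32 µM (1.17 in the authors' deposited table), and with it included the median was -0.05 at each dose. How the name came to this locus stays open.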

How the results depend on the processing

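Alternatives that leave out rows sharing a locus or genes in several lists, and the limit of 0.1 below, were chosen after the data were seen. No paired analysis was possible because the tables give 1 value per group; leaving out each replicate, other splits of the samples and tests on values per sample were not run for the same reason, and an unknown depth limits what can be said of genes not called. At a q-value under 0.01 the authors' test left 0 of 76 calls at 16 µM, 293 of 492 at 32 µM and 0 of 96 between the doses. The recovered p was under 0.05 for at least 388, 3012 and 736 rows, which are minimum counts because tied q-values give upper bounds of p. The smallest q was 0.0219 at 16 µM and 0.0194 between the doses. The smallest p recovered from the authors' test was 5e-05 in each comparison. The counts of 0 therefore reflect how many rows shared that p, and do not show weaker calls than at 32 µM. A change of at least 1.5-fold left 26, 87 and 20 calls (11, 59 and 16 higher), and a change of at least 1 on log2(value + 1) left 10, 14 and 5 (5, 11 and 2 higher). Other alternatives kept each count of calls within 1.5 times. Of these, centring the ratios and redoing the Benjamini-Hochberg adjustment over all rows on recovered p-values could change no count. At 32 µM every row already reached 1 FPKM, so that minimum could change nothing there. At 5 FPKM or more 169 of 373 calls at 32 µM were higher, against 258 of 492, so the majority turned from higher to lower. The correlation of the doses was 0.718 over rows with a q under 0.10 at either dose, and it reversed to -0.22 when each dose took its control value from the other table; over the 10499 rows whose control values differed by at most 0.1 between tables it was 0.548, so the 690 other rows carried the reversal. The number of called lists went from 5 to 9 at 16 µM on log2(value + 1), and with a preset correlation of 0.05 from 10 to 4 at 32 µM and from 5 to 2 between the doses; the cause was not tested. For single planned lists, 528 settings kept the outcome, 18 lost a call, 21 gained one and none turned it. The 324 settings of named genes could not change a direction, so they are no check of it. A pseudocount keeps the sign of a ratio, and the median used for centring was 0.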

Other observations

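The gene lists in this part were put together after the data were seen, partly from genes that had been called, so their counts and camera tests describe these data and are not independent evidence; the p-values are adjusted over 6 such lists. Pigment cell genes fell at 32 µM: 7 of 12 measured genes were called lower and none higher in the authors' deposited table, among them the melanosome gene pmelb (-0.62), the melanin synthesis gene dct (-0.38), tspan36 (-0.31), the transporter gene slc45a2 (-0.27) and the iridophore gene pnp4a (-0.22). The list median was -0.22 at 32 µM (camera adjusted p = 1.32e-05) and -0.14 at 16 µM with none called (adjusted p = 0.0207, but 0.0556 with a preset correlation of 0.05, range over the alternatives 0.00165 to 0.0556). Of 24 complement and coagulation genes, 10 fell at 32 µM in the authors' deposited table, including f7 (-0.37), c8b (-0.36), c3a.6 (-0.30) and c9 (-0.29), with a list median of -0.20 (adjusted p = 1.02e-05). Many of these genes are made by the liver, 6 of the 24 also stand in the liver list, and that list was lower at 32 µM as well (median -0.18), so it is not counted as a separate change. At 16 µM none of 23 was called and the median was -0.06 (adjusted p = 0.0384, but 0.122 with a preset correlation of 0.05 and 0.139 without rows that share a locus, range 0.00508 to 0.139). Genes that light induces in zebrafish or that repair DNA were lower at 32 µM, where 5 of 12 were called in the authors' deposited table. They were tefa (-0.66), the cryptochrome gene cry-dash (-0.49), the photolyase gene cry5 (-0.48), ddb2 (-0.43) and polh (-0.40). Of these, tefa and cry5 also stand in the clock list, so their fall is not counted as a separate change. The median of the light and DNA repair list was -0.17 at 16 µM (adjusted p = 0.00173) and -0.09 at 32 µM (adjusted p = 0.000441, but 0.179 on ranks, range 7.65e-05 to 0.179).

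Immediate early genes, which answer quickly to many stimuli, were lower at 16 µM than in either other group. At 16 µM 4 of 17 fell in the authors' deposited table, nr4a1 (-0.41), sik1 (-0.38), dusp1 (-0.34) and klf2a (-0.31), with a list median of -0.10 (adjusted p = 0.000377). At 32 µM npas4a (0.31) and sik1 (0.19) rose and dusp1 (-0.18) fell in the authors' deposited table, with a list median of 0.07 (adjusted p = 0.0220, but 0.0659 with a preset correlation of 0.05, range 0.00960 to 0.0659). Set directly against 16 µM, 5 of 18 rose at 32 µM, 17 had a positive ratio, and the list median was 0.22 (adjusted p = 3.17e-12); sik1 (0.57), nr4a1 (0.42), npas4a (0.40), klf2a (0.37) and csrnp1b (0.27) were the called genes in the authors' deposited table.

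The narrower arms of clock genes were tested as lists as well. The arm of nr1d, per, dbp, tef, hlf and bhlhe genes had a median of -0.26 at 16 µM (adjusted p = 3.00e-13) and -0.27 at 32 µM (adjusted p = 2.73e-13), with 7 of 14 genes lower at each dose and 1 higher at 32 µM. The arm of arntl, clock, npas2 and nfil3 genes had a median of 0.10 at 16 µM with none of 10 called (adjusted p = 0.152, but 0.0286 on ranks, range 0.0286 to 0.214), and of 0.16 at 32 µM (adjusted p = 4.58e-05), where 4 genes rose in the authors' deposited table.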
